A study of Danio rerio with 36 samples.

How the data were processed

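RNA-seq libraries were made from whole zebrafish embryos and larvae, either wild type or kctd15 mutant, at 6 stages: 1 somite, 25 hpf, 2 day, 5 day, 9 day and 14 day. Each of the 12 groups held 3 biological replicates per the labels, which makes 36 libraries. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded polyA kit. The labels do not say how many animals went into a library or which of the paralogs kctd15a and kctd15b carries the lesion. The RNA of both genes is measured below, but a loss of function need not lower RNA, so it does not check the genotype labels, and a swap of labels between genotypes was not tested.

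The authors trimmed reads with Trimmomatic 0.36, quantified RefSeq transcripts with kallisto 0.43.0 and used edgeR, whose version is not given in the sources used here, per the submitters' processing notes. The deposited gene table and transcript table hold estimated counts (expected counts, not normalized) made by the authors. They list 30490 genes and 54435 transcripts, and 84.1% of the values in the gene table are not whole. The deposited normalized table holds a signal made by the authors: CPM of the genes multiplied by a factor per library, for 23556 gene symbols. Of the 21890 symbols shared with the gene table, 21833 follow the gene counts within 1% in every library, and 57 that do not were left out. The factors range from 0.86 to 1.26 and the column sums of that table from 858666 to 1263101, so its values are close to, but not exactly, CPM. A RefSeq gene table of assembly GRCz12tu was used only for synonyms, gene neighbours and transcript accessions of kctd15a, and no genome sequence was used.

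Estimated counts of the gene table were rounded to whole numbers for every test. Library totals ran from 5.51 to 12.5 M estimated counts. Group means were 9.93 M (wild type) and 10.3 M (mutant) at 1 somite, 9.71 and 6.1 at 25 hpf, 7.36 and 7.24 at 2 day, 6.91 and 8.15 at 5 day, 9.89 and 9.23 at 9 day, and 10.3 and 11.4 at 14 day. The 50 most counted genes held 16.5 to 27.7% of the counts, as group means. No replicate pair was a duplicate: chi-square per degree of freedom between replicates ran from 2.61 to 15.3, and the correlation of log2 CPM across genes from 0.97 to 0.988. The leading 3 principal components held 65.5%, 15.4% and 5.23% of the variance.

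The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Mutant and wild-type libraries were compared at each stage alone with edgeR 4.0.16 (filterByExpr, TMM factors, glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested at that stage and a threshold of 0.05. A fit of all 36 libraries tested the mutant effect averaged over the 6 stages and its interaction with stage (5 degrees of freedom). Consecutive wild-type stages were compared the same way, 5 steps in all. Values after ± are standard errors for log2 fold changes, computed from the fold change and the F statistic, and standard deviations for CPM (n = 3 per group). In each comparison of 3 against 3, chance alone separates the groups completely for 10% of genes.

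Fold changes come from the fit unless a group held few counts. Against a group with 0 counts a fold is a lower bound, computed with 3 counts over the group. For 1 to 3 counts the ratio is given with a 95% counting interval. These bounds and intervals cover counting error only.

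Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01, at stages where at least 5 members were tested, with adjustment over the lists of the stage. The 35 lists hold 957 entries, of which 938 were matched to the gene table, 27 of them through a synonym in the reference. The ribosomal protein list takes rpl and rps symbols without the rps6k kinases, binding proteins ending in bp1 and paralogs ending in l or l1. The gene table holds 0 genes with an mt- symbol. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The mean log2 CPM of a list in a library or group uses the members kept in the fit of all 36 libraries. These are 22 for erythroid, 25 for inflammation and myeloid and 26 for lens crystallin, and can differ from the members tested at a stage. Mean shifts with a library left out use the members tested at the stage.

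Named genes follow a fixed rule. It takes kctd15a, kctd15b, kctd1, tfap2a, tfap2b, tfap2c and tfap2e at every stage. It takes the 10 largest rises and 10 largest falls per stage among called genes whose groups do not overlap, with a mean of at least 1 CPM and a symbol that is not a clone or locus name. It also takes up to 4 called genes per list and stage by smallest p, up to 10 per direction for the averaged effect, up to 10 for the interaction, and the 5 largest changes per direction and wild-type step at a mean of at least 50 CPM. Clone and locus names are left out for the averaged effect, the interaction and the steps too. Of the genes this rule gives, the text prints examples, preferring genes whose call held when any single library was left out. That preference was chosen after seeing the data. The values of 1 gene that the rule gives are not reported here.

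The edgeR fits were tested on simulated data drawn with the means and spreads of the real genes, with 200 genes changed by 1.5-fold, 2-fold or 4-fold. At the 6 stages in order, 78.8%, 86.4%, 67.2%, 73.1%, 76.1% and 58.2% of genes changed by 2-fold were recovered, and 35.8%, 53%, 19.4%, 13.4%, 22.4% and 7.46% of those changed by 1.5-fold. Unchanged genes made up 6.76%, 11.9%, 5.65%, 8.46%, 10.5% and 9.92% of the calls, so the share of false calls can exceed the nominal 5% at this size. The averaged effect recovered 85.1% at 2-fold and the interaction 38.8%. In simulated lists of 25 genes, camera recovered the list shifted by 0.6 log2 at every stage, and 0 of the other lists passed, in data simulated without correlation between genes.

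Alternatives were the replicate number as a block, DESeq2 1.42.0, RLE size factors, library size only, no filter on counts, a filter of 1 CPM in 3 libraries, limma on log2 of the normalized table plus 0.5 or plus 2 for genes with a mean of at least 0.5, one fit of all 36 libraries for the single stages, an estimated inter-gene correlation in camera, fry, and each library left out in turn. Thinning of libraries to one total per stage, and fits without the 25 hpf or 5 day libraries, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.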

Results

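RNA of kctd15a, which encodes a BTB-domain protein known to limit neural crest formation, was higher in kctd15 mutants than in wild type at all 6 stages. Its level went from 89.3 ± 8.44 CPM in wild type to 135 ± 3.81 CPM in mutants at 1 somite (log2 fold change 0.60 ± 0.10), from 23 ± 3.99 to 76.3 ± 8.15 at 25 hpf (1.71 ± 0.11) and from 46.7 ± 6.86 to 166 ± 18.2 at 2 day (1.83 ± 0.14). At 5, 9 and 14 day it was 3.89-fold, 3.86-fold and 3.68-fold higher (log2 1.96 ± 0.17, 1.95 ± 0.11 and 1.88 ± 0.14). Each of these calls held with any 1 library left out, and the edgeR adjusted p ran from 0.00244 at 1 somite to 2.16e-08 at 25 hpf.

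The paralog kctd15b rose by 1.18 ± 0.18 at 2 day (10.1 to 23 CPM, adjusted p = 0.00309). It also passed at 25 hpf (0.64 ± 0.20, adjusted p = 0.0447), 5 day (0.74 ± 0.17, 0.0159), 9 day (1.01 ± 0.16, 0.0132) and 14 day (0.76 ± 0.16, 0.026), but not at 1 somite (-0.18 ± 0.37, 0.801). The 25 hpf call was lost without wild type 1, 2 or 3 or mutant 1 or 3 (adjusted p = 0.127, 0.0501, 0.0927, 0.183 and 0.0945), the 5 day call without wild type 1 or 2 or mutant 2 (0.0601, 0.0502 and 0.081) and the 9 day call without wild type 3 (0.0514). The 14 day call was lost without wild type 2 or 3 or mutant 1, 2 or 3 (0.0708, 0.0854, 0.0513, 0.0637 and 0.0739).

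The closest other family member, kctd1, rose at 25 hpf (1.31 ± 0.29, 1.69 to 4.28 CPM, adjusted p = 0.0048) and did not pass elsewhere (adjusted p 0.147 to 0.976). Among the AP-2 transcription factor genes, whose products KCTD15 is known to bind, tfap2c fell at 25 hpf (-0.56 ± 0.10, 134 to 91.4 CPM, adjusted p = 0.000907) and did not pass at the other stages. Its values were -0.29 ± 0.10, -0.45 ± 0.11 and -0.42 ± 0.11 at 5, 9 and 14 day (edgeR adjusted p = 0.0823, 0.0817 and 0.0654). At 1 somite and 2 day they were 0.03 and 0.05 (edgeR adjusted p = 0.903 and 0.809). tfap2a lay within -0.18 to 0.12 log2 of wild type at every stage, with no adjusted p under 0.447, and neither tfap2b (smallest adjusted p = 0.0608) nor tfap2e (0.17) passed where it was tested. The neural crest list did not pass camera at any stage (adjusted p = 0.609, 0.841, 0.284, 0.658, 0.833 and 0.149 from 1 somite to 14 day).

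**Figure D1:**
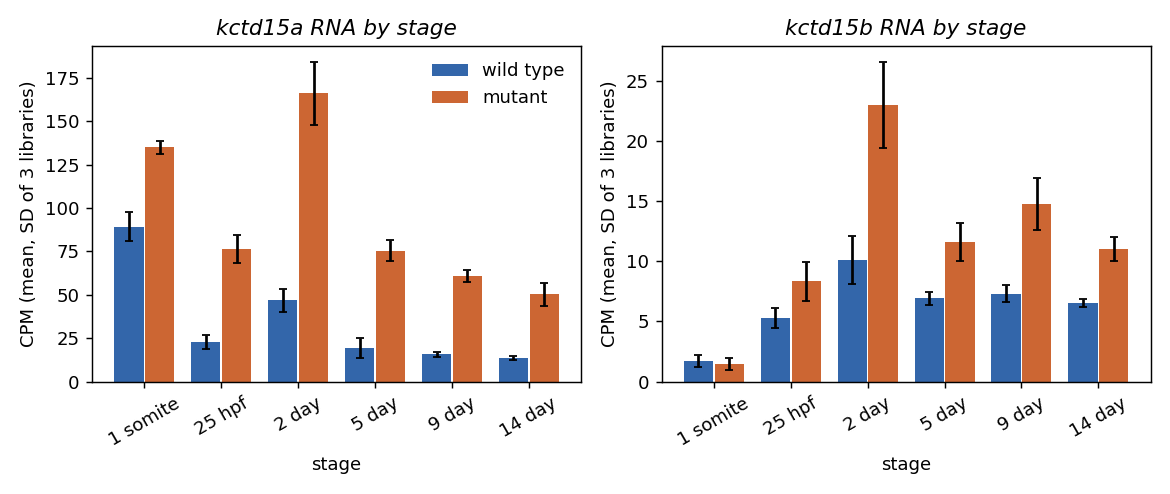
CPM of kctd15a (left) and kctd15b (right) at each stage, as bars of the mean of 3 wild-type and 3 mutant libraries with SD. At 25 hpf and later kctd15a is 3.27-fold to 3.89-fold higher in mutants, while kctd15b at 1 somite shows 1.69 CPM in wild type and 1.45 CPM in mutants.

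At 1 somite, genes for chaperones and the response to unfolded protein were lower in mutants. The Hsp90 gene hsp90aa1.2 went from 127 ± 17.7 to 14.6 ± 1.95 CPM (log2 -3.12 ± 0.14, adjusted p = 3.55e-07), the inducible chaperone hsp70.1 changed by -2.70 ± 0.28, the ER chaperone hsp90b1 by -1.41 ± 0.12 and the stress-induced gene ddit4 by -1.18 ± 0.11. ahsa1a, which encodes a cochaperone of Hsp90, changed by -4.53 ± 0.42. Of 24 members of the heat shock and ER stress list, 1 rose, 12 fell and 11 did not pass (1 and 13 adjusted over the list alone). The median was -0.39 and the camera adjusted p = 9.07e-06, against adjusted p = 0.304 with an estimated correlation.

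Among 13 preplacodal and otic genes at 1 somite, 3 fell, including the placode regulators foxi1 (-0.70 ± 0.11) and six4a (-0.65 ± 0.13), and 10 did not pass (4 lower adjusted over the list alone). The median was -0.22, the camera adjusted p = 0.0312, and adjusted p = 0.834 with an estimated correlation. The camera call was lost without wild type 1 (0.147), mutant 1 (0.219) or mutant 2 (0.0505). None of 72 ribosomal protein genes passed in edgeR (0 adjusted over the list alone; 6 lower and 0 higher at an unadjusted p under 0.05), with a median of -0.19, camera adjusted p = 0.000294 and adjusted p = 0.834 with an estimated correlation, and this call was lost without mutant 1 (0.589).

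Genes outside the called lists at 1 somite included the BMP target id3 (-0.79 ± 0.11), the mesoderm regulator tb (0.68 ± 0.13), the germ cell genes ddx4 (-1.43 ± 0.18) and nanos3 (-1.01 ± 0.23; 2 of 20 list genes rose and 4 fell), the glutathione transferase gstp1 (-2.32 ± 0.11) and the epidermal genes anxa1a (-1.92 ± 0.17), icn (-1.70 ± 0.18) and cldni (1.48 ± 0.14; 1 of 23 list genes rose and 4 fell). Among the largest rises were faah, a hydrolase of fatty acid amides, at least 65.6-fold higher (0 counts in wild type, 214 in mutants), and the relaxin receptor gene rxfp2a at 180-fold (counting interval 49.6 to 1490). Also higher were map6a at 98-fold (26.8 to 814), cyp4v7 at 67.1-fold (18.3 to 560) and the heparan sulfatase gene sulf2b at 21.2-fold (log2 4.40 ± 0.29). Among the largest falls were cnn1a, at least 31.5-fold lower, kbtbd7, at least 27.9-fold lower, cel.1 at 69.6-fold (12 to 2790), unc80 at 33.3-fold (11.1 to 165), and wtip (log2 -4.70 ± 0.38).

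In all, 2285 of 16844 genes tested at 1 somite (13.6%) passed in edgeR, 1141 higher and 1144 lower, 538 and 470 of them by 2-fold or more. Over all genes tested the groups did not overlap for 32.2% (chance gives 10%). Scaled by library size only, the split was 1395 higher and 915 lower. The count was 1424 without wild type 1, 1502 without mutant 1 and 1397 without mutant 3. Of 86 named genes called, 62 kept the call with any 1 library left out.

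At 25 hpf, most genes of the embryonic red blood cell were higher in mutants, with the largest median shift of any list at this stage. The embryonic globin genes hbae3 and hbbe3 went from 252 ± 43.6 to 1040 ± 156 CPM (log2 2.06 ± 0.12, adjusted p = 2.78e-09) and from 252 to 988 CPM (1.97 ± 0.11), hbae1 rose by 2.88 ± 0.30 and the erythrocyte carbonic anhydrase cahz by 1.86 ± 0.09. Of 20 erythroid genes, 17 rose, 1 fell and 2 did not pass (18 and 1 adjusted over the list alone), with a median of 1.70. The gene that fell was the globin hbbe1.1, called lower at 5 stages and higher at none. The mean log2 CPM of the list was 5.48 ± 0.18 in mutants and 4.19 ± 0.10 in wild type. The camera adjusted p = 4.59e-17, and adjusted p = 0.275 with an estimated correlation.

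Fast muscle genes rose at 25 hpf: 22 of 26 (24 adjusted over the list alone) and 0 fell, with a median of 0.59 (camera adjusted p = 4.42e-16; adjusted p = 0.371 with an estimated correlation). Examples are the calcium buffer gene pvalb1 (1.48 ± 0.09, 197 to 549 CPM) and its relative pvalb3 (1.37 ± 0.11), and the troponin gene tnnt3b (1.06 ± 0.08). Of 16 lens crystallin genes 12 rose (12 adjusted over the list alone), among them the lens water channel genes mipb (1.72 ± 0.16) and mipa (0.76 ± 0.11), with a median of 0.58 (adjusted p = 5.03e-08; adjusted p = 0.393 with an estimated correlation). Of 22 pigment cell genes 12 rose and 0 fell (13 and 0 adjusted over the list alone), among them gch2 of pteridine synthesis (0.69 ± 0.08) and the melanin synthesis genes tyrp1a (0.68 ± 0.09) and tyrp1b (0.47 ± 0.08). The pigment median was 0.38 (adjusted p = 4.34e-06; adjusted p = 0.275 with an estimated correlation).

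Other lists passed camera as higher at 25 hpf as well. Of 25 liver genes 12 rose and 1 fell (16 and 1 adjusted over the list alone), such as the retinol carrier rbp4 (0.72 ± 0.11) and the clotting factor f2 (0.71 ± 0.11). For liver genes the median was 0.34 and the camera adjusted p = 6.63e-05, but adjusted p = 0.571 with an estimated correlation. Of 15 intestine genes 7 rose (9 adjusted over the list alone), such as the apolipoprotein gene apoa4b.2 (1.18 ± 0.11). For intestine genes the median was 0.28 and the camera adjusted p = 0.000155, but adjusted p = 0.393 with an estimated correlation. Of 38 neuronal genes 7 rose (8 adjusted over the list alone), such as stmn1b (0.35 ± 0.08) and snap25a (0.34 ± 0.08). For neuronal genes the median was 0.30 and the camera adjusted p = 6.63e-05, but adjusted p = 0.328 with an estimated correlation. Of 30 circadian clock genes 8 rose (10 adjusted over the list alone), such as cry1ab (1.05 ± 0.17) and per1b (0.66 ± 0.10). For circadian clock genes the median was 0.20 and the camera adjusted p = 0.00399, but adjusted p = 0.402 with an estimated correlation. Of 5 exocrine pancreas genes 1 rose (3 adjusted over the list alone). For exocrine pancreas genes the median was 0.64 and the camera adjusted p = 0.00651, but adjusted p = 0.328 with an estimated correlation.

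Of 24 cholesterol biosynthesis genes 4 fell at 25 hpf (4 adjusted over the list alone), among them sqlea (-1.21 ± 0.25) and fdps (-0.43 ± 0.09), with a median of -0.24 (adjusted p = 0.00736; adjusted p = 0.393 with an estimated correlation), a call lost without mutant 3 (0.0891). Ribosomal protein genes had a median of 0.11, with 3 of 72 risen (0 adjusted over the list alone; adjusted p = 0.000306; adjusted p = 0.763 with an estimated correlation), lost without wild type 2 (0.142), and the median was 0.04 with library size only. Also lower were the paraxial mesoderm genes tbx6 (-1.35 ± 0.26) and pcdh8 (-1.70 ± 0.30; 1 of 22 list genes rose and 3 fell), the epithelial gene anxa1b (-1.67 ± 0.11, 118 to 36.9 CPM) and the neural crest marker crestin (-0.54 ± 0.09). In the neural crest list, 1 of 27 genes rose and 2 fell at this stage. Among the largest falls were btr07, at least 33.2-fold lower, kbtbd7, at least 30.4-fold lower (152 counts in wild type, 0 in mutants), and the FK506-binding protein gene fkbp16 (log2 -4.50 ± 0.28). Among the largest rises were plac8l1 (4.58 ± 0.51), cbln11 (3.85 ± 0.22) and cyp4v7 (3.79 ± 0.48).

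At 25 hpf 2564 of 18898 genes (13.6%) passed in edgeR, 1288 higher and 1276 lower, 358 and 362 by 2-fold or more, and over all genes tested the groups did not overlap for 30.3% (chance gives 10%). Mutant libraries of this stage were shallower (5.51 to 6.67 M counts) than wild type (7.93 to 10.8 M). By library size only the split was 984 higher and 1740 lower. Of 116 named genes called, 85 kept the call with any 1 library left out.

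At 2 day the erythroid difference was still present. The embryonic globin hbbe2 went from 21 ± 11.5 to 106 ± 17 CPM (log2 2.33 ± 0.32, adjusted p = 0.00196), the heme synthesis gene alas2 from 27.3 ± 17.3 to 133 ± 19.7 CPM (2.29 ± 0.39) and the transferrin receptor tfr1a rose by 1.40 ± 0.19. Of 19 erythroid genes 14 rose, 1 fell and 4 did not pass (15 and 1 adjusted over the list alone), with a median of 1.40 (camera adjusted p = 1.45e-06; adjusted p = 0.789 with an estimated correlation). The gene that fell was again hbbe1.1. The mean log2 CPM of the list was 5.30 ± 0.11 in mutants and 4.15 ± 0.76 in wild type, where wild type 2 stood lowest at 3.27.

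Intestine genes rose at 2 day in 7 of 17 cases and fell in 1 (11 and 2 adjusted over the list alone), led by apoa4b.2 (4.59-fold, 85.4 to 392 CPM) and the fatty acid binding protein fabp2 (1.01 ± 0.18). The rise of apoa4b.2 was not confined to stages with an intestine list call. It also passed in edgeR at 1 somite (0.87 ± 0.11) and 5 day (0.61 ± 0.11), but not at 9 and 14 day. For intestine genes the median was 0.72 and the camera adjusted p = 0.00146, but adjusted p = 0.789 with an estimated correlation. Ionocyte and epidermis genes rose in 8 of 27 cases and fell in 1 (11 and 2 adjusted over the list alone), with the keratin genes krt17 (1.95 ± 0.26) and cyt1l (0.93 ± 0.14) and the carbonic anhydrase ca15a (2.15 ± 0.20). For ionocyte and epidermis genes the median was 0.40 and the camera adjusted p = 0.00319, but adjusted p = 0.789 with an estimated correlation. Of 20 immediate early genes 6 rose (9 adjusted over the list alone), with npas4a (2.87 ± 0.45) and nr4a1 (0.96 ± 0.15), transcription factors induced by neuronal activity and other stimuli. For immediate early genes the median was 0.52 and the camera adjusted p = 0.00519, but adjusted p = 0.789 with an estimated correlation. That call was lost without wild type 3 (0.0887) or mutant 2 (0.078). Of 23 gluconeogenesis and fasting genes 3 rose and 1 fell (10 and 1 adjusted over the list alone). For gluconeogenesis and fasting genes the median was 0.32 and the camera adjusted p = 0.0291, but adjusted p = 0.718 with an estimated correlation, a call lost without wild type 3 (0.141) or mutant 3 (0.0728).

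Lists that passed camera as lower at 2 day held few single genes past the threshold. Of 42 neuronal genes 3 fell (5 adjusted over the list alone), among them sncga (-1.02 ± 0.17). For neuronal genes the median was -0.21 and the camera adjusted p = 0.00319, but adjusted p = 0.952 with an estimated correlation, a call lost without mutant 1 (0.439). Of 22 glia and myelin genes 1 fell (2 higher and 8 lower adjusted over the list alone). For glia and myelin genes the median was -0.33 and the camera adjusted p = 0.00519, but adjusted p = 0.715 with an estimated correlation. Of 24 cholesterol biosynthesis genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), with hsd17b7 at -0.77 ± 0.15. For cholesterol biosynthesis genes the median was -0.27 and the camera adjusted p = 0.00536, but adjusted p = 0.789 with an estimated correlation. None of 34 cell cycle genes passed in edgeR (0 adjusted over the list alone; 1 higher and 4 lower at an unadjusted p under 0.05). For cell cycle genes the median was -0.14 and the camera adjusted p = 0.0174, but adjusted p = 0.952 with an estimated correlation, a call lost without wild type 2 (0.0997), mutant 2 (0.248) or mutant 3 (0.058).

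Other genes at 2 day included klf9 (1.64 ± 0.25) and cebpd (1.26 ± 0.21), the 2 genes risen of 12 in the glucocorticoid response list (4 adjusted over the list alone), which did not pass camera (adjusted p = 0.0881). They also included the chaperone hsp70l (2.63 ± 0.44), the iron hormone gene hamp (-2.14 ± 0.21) and the hypertrophic cartilage collagen col10a1a (-0.94 ± 0.13). Among the largest rises were the ammonium transporter rhcga (4.20 ± 0.57), arpp19b (4.06 ± 0.73) and plac8l1 (3.94 ± 0.45). Among the largest falls were kbtbd7 at 74.7-fold (counting interval 20.3 to 623), ggact.2 (log2 -5.52 ± 0.35) and btr07 (-5.03 ± 0.71). In all, 1388 of 20229 genes (6.86%) passed in edgeR, 950 higher and 438 lower, 472 and 151 by 2-fold or more, and over all genes tested the groups did not overlap for 30% (chance gives 10%). The fit of all 36 libraries gave 1308 higher and 1708 lower at this stage. The count was 555, 583 and 2497 without wild type 1, 2 and 3, and 836 and 564 without mutant 2 and 3. Of 87 named genes called, 49 kept the call with any 1 library left out.

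At 5 day, genes of inflammation and of the response to interferon were lower in mutants than in wild type. hamp went from 29.2 ± 11.4 to 0.376 ± 0.651 CPM (78.9-fold, log2 -6.30 ± 0.61, adjusted p = 0.000107), the macrophage gene irg1 from 23.7 to 0.673 CPM (-5.14 ± 0.29) and the matrix metalloproteinase gene mmp9 from 31.2 to 6.56 CPM (-2.24 ± 0.15). Of 23 inflammation and myeloid genes 1 rose, 18 fell and 4 did not pass (1 and 20 adjusted over the list alone). For inflammation and myeloid genes the median was -1.34 and the camera adjusted p = 2.45e-13, but adjusted p = 0.574 with an estimated correlation. The mean log2 CPM of the list was 3.98 ± 0.26 in wild type and 2.42 ± 0.19 in mutants, and 2.29 to 2.94 in either genotype at 2 and 9 day.

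Of 16 interferon response genes 1 rose, 12 fell and 3 did not pass at 5 day (1 and 12 adjusted over the list alone). For interferon response genes the median was -1.70 and the camera adjusted p = 9.79e-08, but adjusted p = 0.574 with an estimated correlation. Examples are the antiviral GTPase gene mxc (-3.09 ± 0.24), the transcription factor irf1b (-2.87 ± 0.25, 61.9 to 8.31 CPM), the RNA sensor dhx58 (-2.10 ± 0.25) and the peptide transporter tap1 (-1.79 ± 0.25). mxf was 270-fold lower (counting interval 92.2 to 1310), and the chemokine genes cxcl19 (-3.98 ± 0.45) and ccl34a.4 (18.1-fold lower, 5.87 to 90.7) were among the largest falls. Of 26 xenobiotic response genes 12 fell and 0 rose (15 lower and 1 higher adjusted over the list alone), among them the aryl hydrocarbon receptor targets cyp1a (-1.97 ± 0.16, 188 to 48.1 CPM) and cyp1c1 (-1.04 ± 0.14). For xenobiotic response genes the median was -0.42 and the camera adjusted p = 1.17e-05, but adjusted p = 0.574 with an estimated correlation. Of 25 cholesterol biosynthesis genes 4 fell (5 adjusted over the list alone), among them hmgcra of the rate-limiting step (-1.47 ± 0.22). For cholesterol biosynthesis genes the median was -0.31 and the camera adjusted p = 0.00239, but adjusted p = 0.574 with an estimated correlation, a call lost without wild type 3 (0.065).

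Ribosomal protein genes rose at 5 day in 57 of 73 cases, with 0 fallen and 16 not past (70 higher adjusted over the list alone), by a median of 0.34 (camera adjusted p = 9.33e-18; adjusted p = 0.574 with an estimated correlation). Examples are rps2 (0.52 ± 0.07, 2020 to 2890 CPM) and rpl6 (0.49 ± 0.08). Fast muscle genes rose in 17 of 27 cases and fell in 1 (19 and 1 adjusted over the list alone), led by the actin gene acta1b (1.71 ± 0.10, 367 to 1200 CPM) and the myosin gene myhz1.2 (0.81 ± 0.07). For fast muscle genes the median was 0.43 and the camera adjusted p = 3.61e-08, but adjusted p = 0.574 with an estimated correlation. Of 34 cell cycle genes 7 rose (8 adjusted over the list alone), such as the replication helicase subunit mcm7 (0.70 ± 0.12). For cell cycle genes the median was 0.33 and the camera adjusted p = 5.65e-05, but adjusted p = 0.574 with an estimated correlation. Of 21 immediate early genes 8 rose and 1 fell (10 and 2 adjusted over the list alone), such as npas4a (2.29 ± 0.18) and egr1 (1.09 ± 0.16). For immediate early genes the median was 0.42 and the camera adjusted p = 0.00239, but adjusted p = 0.574 with an estimated correlation.

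Smaller shifts at 5 day were those of neuronal genes, where 3 of 43 rose and 1 fell (2 and 1 adjusted over the list alone), with elavl3 at 0.50 ± 0.09. For neuronal genes the median was 0.22 and the camera adjusted p = 0.000824, but adjusted p = 0.731 with an estimated correlation. Of 22 exocrine pancreas genes 4 rose (6 higher and 1 lower adjusted over the list alone), such as cel.2 (0.58 ± 0.09). For exocrine pancreas genes the median was 0.19 and the camera adjusted p = 0.012, but adjusted p = 0.671 with an estimated correlation, a call lost without wild type 2 (0.119). Of 39 phototransduction genes 4 rose and 3 fell (6 and 4 adjusted over the list alone), with the arrestin gene sagb at 0.77 ± 0.13 and guk1b at -0.85 ± 0.16. For phototransduction genes the median was 0.27 and the camera adjusted p = 0.0129, but adjusted p = 0.787 with an estimated correlation, a call lost without wild type 2 (0.184) or mutant 1 (0.219). Of 31 feeding and hypothalamic peptide genes 1 rose (1 adjusted over the list alone). For feeding and hypothalamic peptide genes the median was 0.18 and the camera adjusted p = 0.0199, but adjusted p = 0.574 with an estimated correlation. Of 21 kctd family genes 2 rose, kctd15a and kctd15b (2 adjusted over the list alone). Both count in the camera test, and the list was not tested without them. For kctd family genes the median was 0.18 and the camera adjusted p = 0.0288, but adjusted p = 0.574 with an estimated correlation, a call lost without wild type 2 (0.119) or mutant 1 (0.0602). With library size only the median of all genes at 5 day was -0.17, and the list medians were 0.17 for ribosomal protein, 0.26 for fast muscle, 0.04 for neuronal, 0.02 for exocrine pancreas, 0.1 for phototransduction, 0.16 for cell cycle, 0.25 for immediate early, 0.01 for the feeding and kctd lists and -0.48 for cholesterol biosynthesis.

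Outside these lists, 5 day mutants had higher RNA of the epidermal keratin genes cyt1l (2.35 ± 0.18, 423 to 2150 CPM), cyt1 (1.81 ± 0.16) and krtt1c19e (1.63 ± 0.11). Clock genes went both ways, per1b by 1.37 ± 0.13 and nr1d4b by -2.97 ± 0.29. In this list 9 of 34 genes rose and 8 fell, where 14% of all genes tested were called. Camera gave no call (adjusted p = 0.338), but it asks for a shift in one direction and cannot see a change in both. The glucocorticoid target fkbp5 was lower (-2.49 ± 0.36, 164 ± 77.7 to 28.8 ± 13.8 CPM; 1 of 12 list genes rose and 2 fell), as were the p53 target cdkn1a (-2.05 ± 0.21) and the complement genes c3a.1 (-1.21 ± 0.13) and c9 (-1.04 ± 0.16). Among the largest rises were pcdh2g1 (4.36 ± 0.64), arpp19b (4.13 ± 0.70) and fabp11b (3.87 ± 0.75).

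At 5 day 3014 of 21510 genes (14%) passed in edgeR, 1328 higher and 1686 lower, 223 and 765 by 2-fold or more, and over all genes tested the groups did not overlap for 33.1% (chance gives 10%). With library size only the split was 569 higher and 3586 lower. The count was 1662, 1754 and 4723 without wild type 1, 2 and 3, and 1711 and 1381 without mutant 1 and 2. Of 122 named genes called, 84 kept the call with any 1 library left out.

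At 9 day fewer genes passed. The chaperone gene hsp70l went from 1.16 to 10.1 CPM (log2 3.12 ± 0.33, adjusted p = 0.00169), hsp90aa1.1 rose by 0.69 ± 0.10 and the small heat shock protein gene hspb1 by 0.73 ± 0.12. Of 27 heat shock and ER stress genes 4 rose and 0 fell (8 and 0 adjusted over the list alone). For heat shock and ER stress genes the median was 0.22 and the camera adjusted p = 0.000553, but adjusted p = 0.277 with an estimated correlation. The light-induced clock gene per2 rose by 1.14 ± 0.13 (119 to 261 CPM), and of 34 circadian clock genes 3 rose (7 higher and 1 lower adjusted over the list alone). For circadian clock genes the median was 0.16 and the camera adjusted p = 0.00194, but adjusted p = 0.55 with an estimated correlation.

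Of 22 lens crystallin genes 4 rose at 9 day (16 adjusted over the list alone), and the list stood at 4.63 ± 0.14 mean log2 CPM in mutants and 4.21 ± 0.24 in wild type. For lens crystallin genes the median was 0.57 and the camera adjusted p = 1.08e-08, but adjusted p = 0.55 with an estimated correlation. Of 39 phototransduction genes 1 rose and 2 fell (3 and 2 adjusted over the list alone), with the green cone opsin opn1mw2 at -0.86 ± 0.11. For phototransduction genes the median was 0.28 and the camera adjusted p = 0.00028, but adjusted p = 0.75 with an estimated correlation. Of 34 cell cycle genes 1 rose (2 adjusted over the list alone). For cell cycle genes the median was 0.21 and the camera adjusted p = 9.66e-06, but adjusted p = 0.277 with an estimated correlation. None of 43 neuronal genes passed in edgeR (0 adjusted over the list alone; 7 higher and 1 lower at an unadjusted p under 0.05). For neuronal genes the median was 0.18 and the camera adjusted p = 0.0013, but adjusted p = 0.75 with an estimated correlation, a call lost without wild type 1 (0.155). Of 20 kctd family genes 2 rose, kctd15a and kctd15b (2 adjusted over the list alone). Both count in the camera test, and the list was not tested without them. For kctd family genes the median was 0.22 and the camera adjusted p = 0.00149, but adjusted p = 0.277 with an estimated correlation.

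Of 23 exocrine pancreas genes 2 fell at 9 day (1 higher and 4 lower adjusted over the list alone), among them the lipase gene cel.1 (-1.01 ± 0.13). For exocrine pancreas genes the median was -0.27 and the camera adjusted p = 0.00205, but adjusted p = 0.75 with an estimated correlation, a call lost without wild type 1 (0.108). Of 20 interferon response genes 2 fell (3 adjusted over the list alone). For interferon response genes the median was -0.29 and the camera adjusted p = 0.00231, but adjusted p = 0.55 with an estimated correlation. Of 31 liver genes 1 fell (1 adjusted over the list alone). For liver genes the median was -0.12 and the camera adjusted p = 0.0254, but adjusted p = 0.6 with an estimated correlation, a call lost without wild type 1 (0.0562), wild type 3 (0.0811), mutant 2 (0.131) or mutant 3 (0.0735). cyp1a (-1.17 ± 0.12) and the quinone reductase nqo1 (-0.72 ± 0.10) fell. The largest falls included the class I histocompatibility gene mhc1lfa, at least 58.8-fold lower, ecm1a, at least 41.3-fold lower, and the immunity-related GTPase gene irgf3 (-3.56 ± 0.47), and the largest rises rxfp2a (2.88 ± 0.19), rnh1 (2.23 ± 0.29) and the Notch target her15.1 (1.60 ± 0.23).

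In edgeR 422 of 22143 genes (1.91%) passed at 9 day, 174 higher and 248 lower, 74 and 185 by 2-fold or more, and over all genes tested the groups did not overlap for 21.5% (chance gives 10%). Scaled by library size only, the split was 132 higher and 331 lower. The count was 244 without wild type 3, and 205, 269 and 221 without mutant 1, 2 and 3. Of 47 named genes called, 21 kept the call with any 1 library left out.

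At 14 day the known glucocorticoid target fkbp5 went from 94.5 ± 26.2 to 476 ± 8.88 CPM (log2 2.33 ± 0.18, adjusted p = 0.000178), klf9 rose by 1.70 ± 0.26, per1a by 1.27 ± 0.14 and hsd11b2, which inactivates cortisol, by 1.01 ± 0.15. Of 12 glucocorticoid response genes 4 rose (4 adjusted over the list alone). For glucocorticoid response genes the median was 0.19 and the camera adjusted p = 0.0158, but adjusted p = 0.847 with an estimated correlation, a call lost without wild type 1 (0.0708) or mutant 3 (0.276). Of 33 circadian clock genes 8 rose and 0 fell (13 and 0 adjusted over the list alone), such as cry1ab (1.47 ± 0.18), hlfa (1.11 ± 0.14) and tefb (1.09 ± 0.13). For circadian clock genes the median was 0.27 and the camera adjusted p = 1.57e-05, but adjusted p = 0.847 with an estimated correlation. Of 24 gluconeogenesis and fasting genes 5 rose (8 adjusted over the list alone), such as the pyruvate dehydrogenase kinase gene pdk4 (1.14 ± 0.13) and foxo3b (0.97 ± 0.12). For gluconeogenesis and fasting genes the median was 0.39 and the camera adjusted p = 0.000545, but adjusted p = 0.847 with an estimated correlation.

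Of 26 lens crystallin genes 5 rose at 14 day (13 higher and 2 lower adjusted over the list alone), led by crygm4 (2.65 ± 0.45). The list stood at 6.23 mean log2 CPM in mutant 3, against 5.54 and 5.45 in mutants 1 and 2 and 5.02 to 5.34 in wild type. For lens crystallin genes the median was 0.56 and the camera adjusted p = 0.000545, but adjusted p = 0.868 with an estimated correlation. Of 43 neuronal genes 0 passed in edgeR (0 adjusted over the list alone; 10 higher and 1 lower at an unadjusted p under 0.05). For neuronal genes the median was 0.29 and the camera adjusted p = 0.001, but adjusted p = 0.878 with an estimated correlation. Of 39 phototransduction genes 2 rose (2 adjusted over the list alone). For phototransduction genes the median was 0.33 and the camera adjusted p = 0.004, but adjusted p = 0.878 with an estimated correlation, a call lost without wild type 2 (0.0658) or mutant 3 (0.359). Of 25 cholesterol biosynthesis genes 1 rose (1 adjusted over the list alone). For cholesterol biosynthesis genes the median was 0.23 and the camera adjusted p = 0.0389, but adjusted p = 0.878 with an estimated correlation, a call lost without wild type 3 (0.432), mutant 1 (0.293) or mutant 2 (0.0998).

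Of 24 interferon response genes 2 fell at 14 day (14 adjusted over the list alone), and mxg, of the same antiviral family as mxc, changed by -4.29 ± 0.57. For interferon response genes the median was -0.95 and the camera adjusted p = 0.000598, but adjusted p = 0.847 with an estimated correlation. The list stood at 2.04 ± 0.03 mean log2 CPM in mutants and 2.97 ± 0.85 in wild type, where wild type 2 reached 3.94, and the mean shift went from -0.95 to -0.50 without it. Of 22 inflammation and myeloid genes 4 fell (6 adjusted over the list alone). For inflammation and myeloid genes the median was -0.32 and the camera adjusted p = 0.0306, but adjusted p = 0.847 with an estimated correlation, a call lost without wild type 1 (0.0547), mutant 1 (0.057) or mutant 2 (0.0752). Of 15 bone genes 2 fell (7 adjusted over the list alone). For bone genes the median was -0.45 and the camera adjusted p = 0.00456, but adjusted p = 0.847 with an estimated correlation. Of 27 heat shock and ER stress genes 1 rose and 4 fell (1 and 5 adjusted over the list alone), among them the collagen chaperone serpinh1b (-2.12 ± 0.14, 435 to 100 CPM). For heat shock and ER stress genes the median was -0.12 and the camera adjusted p = 0.0382, but adjusted p = 0.847 with an estimated correlation, a call lost without wild type 1 (0.0826), wild type 2 (0.115), mutant 1 (0.132) or mutant 2 (0.0573).

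Other genes at 14 day were the myosin gene myha (-1.51 ± 0.22), the xenobiotic receptor nr1i2 (2.01 ± 0.17), and the junction genes itgb4 (2.28 ± 0.19) and dsc2l (2.05 ± 0.20), which were among the largest rises with hel_dr1 (33.5-fold, counting interval 11.2 to 165). The largest falls included ecm1a, at least 47-fold lower, mhc1lfa at 182-fold (32.3 to 7240), casp6l2 at 55.7-fold (18.7 to 273) and kbtbd7 at 54.3-fold (14.6 to 454). In edgeR 1073 of 22335 genes (4.8%) passed, 515 higher and 558 lower, 245 and 349 by 2-fold or more, and over all genes tested the groups did not overlap for 27.2% (chance gives 10%). The count was 667 and 556 without wild type 2 and 3, and 559 and 646 without mutant 1 and 3. Of 75 named genes called, 38 kept the call with any 1 library left out.

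**Figure D2:**
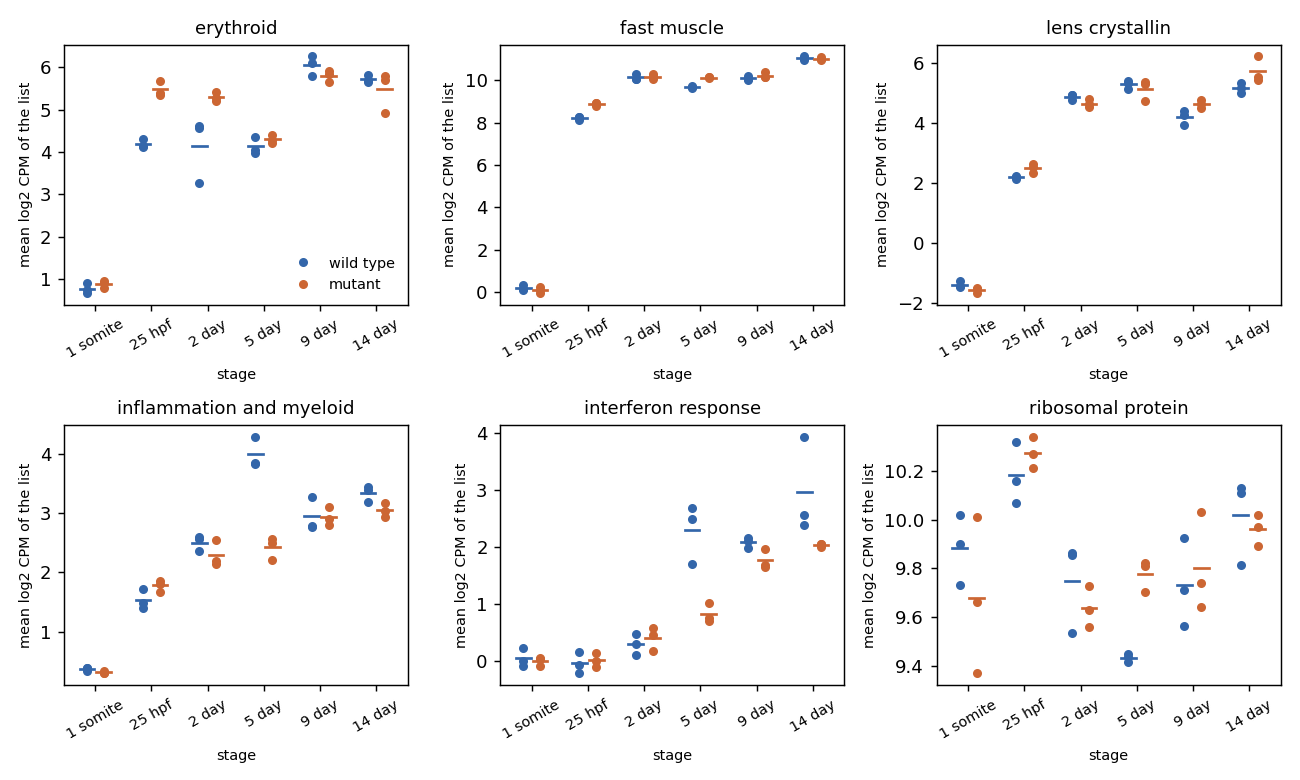
Mean log2 CPM of 6 gene lists in each of the 36 libraries by stage, points for libraries and short lines for the mean of 3. Each mean is over the members kept in the fit of all 36 libraries. The erythroid points of 25 hpf mutants lie above those of 25 hpf wild type (means 5.48 and 4.19), and the inflammation points of 5 day wild type lie above those of 5 day mutants (3.98 and 2.42).

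At every stage but 25 hpf, another split of the same libraries gave at least as many lists past camera as the real one. All 57 lists past camera over the 6 stages kept the sign of their mean shift with any 1 library left out, and 18 moved by over 1.5 times. The shift went from -0.21 to -0.07 without mutant 1 for ribosomal protein at 1 somite. At 25 hpf it went from 0.33 to 0.20 without wild type 1 for liver and from 0.11 to 0.05 without wild type 2 for ribosomal protein. At 2 day it went from 1.39 to 0.91 without wild type 2 for erythroid, from -0.24 to -0.06 without mutant 1 for neuronal and from -0.14 to -0.07 without mutant 2 for cell cycle. At 5 day it went from 0.22 to 0.14 without wild type 2 for exocrine pancreas, from 0.24 to 0.37 without wild type 3 for neuronal and from 0.21 to 0.09 without mutant 1 for phototransduction. Without wild type 1 at 9 day it went from -0.25 to -0.12 for exocrine pancreas, from 0.16 to 0.06 for neuronal and from 0.27 to 0.12 for phototransduction. Without mutant 3 at 14 day it went from 0.55 to 0.31 for lens crystallin, from 0.48 to 0.30 for gluconeogenesis and fasting, from 0.28 to 0.16 for neuronal and from 0.34 to 0.12 for phototransduction. The 14 day shifts of interferon response went from -0.95 to -0.50 without wild type 2, and of cholesterol biosynthesis from 0.21 to 0.08 without wild type 3.

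Lists that passed camera at no stage, with their smallest camera adjusted p, were neural crest specification (0.149 at 14 day), canonical Wnt targets (0.0617 at 5 day), cartilage (0.0998 at 5 day), germ line and maternal (0.248 at 9 day), fatty acid synthesis and lipid storage (0.41 at 9 day), p53 response (0.292 at 5 day), pituitary hormone (0.217 at 5 day) and segmentation and paraxial mesoderm (0.146 at 25 hpf). The vitellogenin list had fewer than 5 tested members at every stage and was not tested. Immediate early genes had medians of 0.63 at 9 day and 0.65 at 14 day without passing (adjusted p = 0.232 and 0.146), where mutant 3 stood at 4.92 and 5.68 mean log2 CPM against 3.49 ± 0.16 and 3.95 ± 0.12 in wild type. With an estimated correlation camera passed 0 lists at each of the 6 stages (1, 4, 2, 1, 3 and 0 lists at an unadjusted p under 0.05), and fry, which tests a list without comparing it with other genes, passed 3, 13, 2, 6, 3 and 0 lists from 1 somite to 14 day. The lists past fry include canonical Wnt targets, lower at 1 somite (fry adjusted p = 0.00704). They also include segmentation and paraxial mesoderm, lower at 25 hpf (fry adjusted p = 0.0437).

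**Figure D3:**
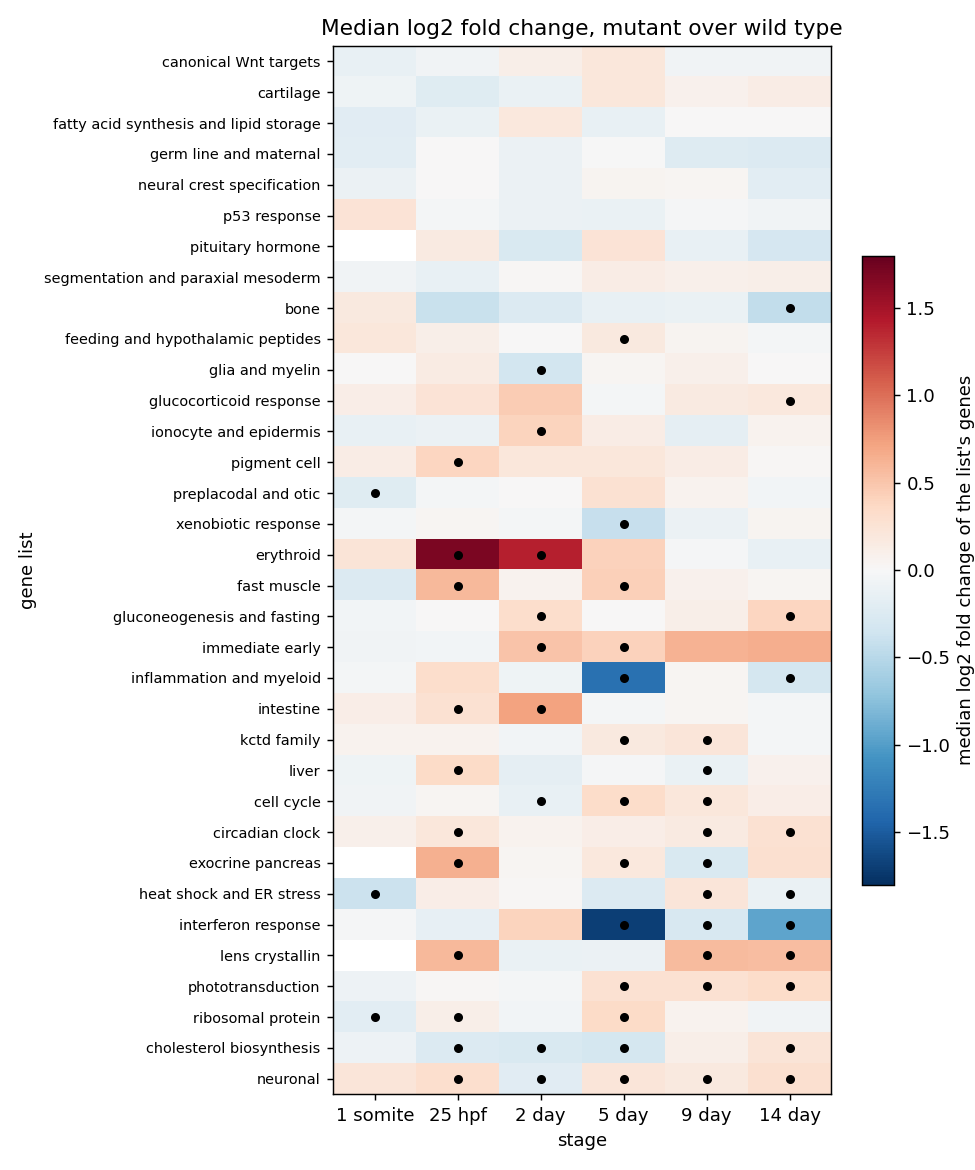
Median log2 fold change (mutant over wild type) of each gene list at each stage, as colour, with a dot where camera passed and white where fewer than 5 members were tested. Erythroid genes have medians of 1.70 at 25 hpf and 1.40 at 2 day, and interferon response genes -1.70 at 5 day and -0.95 at 14 day.

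Averaged over the 6 stages, kctd15a had the smallest p among genes that rose and carry no clone or locus symbol (1.65 ± 0.06, adjusted p = 3.11e-20), ahead of rxfp2a, sulf2b, faah and the histamine synthesis gene hdc. Much of these averages came from 1 somite. sulf2b averaged 0.99 ± 0.06, with 4.40 at 1 somite and 0.18 to 0.39 later (not past at 2, 9 and 14 day), and hdc 0.98 ± 0.08, with 3.19 at 1 somite and 0.26 to 0.77 later (not past from 5 day on). For rxfp2a and faah, with 2 and 0 wild-type counts at 1 somite, an average fold has no exact value. After 1 somite rxfp2a changed by 0.90 to 3.56 (not past at 25 hpf) and faah by 0.60 to 2.76 (not past from 5 day on). Among genes that fell, the autophagy gene map1lc3b changed by -1.18 ± 0.04 (adjusted p = 3.11e-20) and passed at each of the 6 stages with values of -1.31, -1.11, -1.33, -1.16, -0.94 and -1.15. The glutathione transferase family gene mgst2 (-1.16 ± 0.06; -2.60 at 1 somite, not past at 2 day), the carbonyl reductase family gene cbr1l (-0.82 ± 0.06, past at each stage), galk2 (-1.05 ± 0.08, not past at 9 and 14 day) and bnip4 (-2.03 ± 0.17, not past at 2 day) also fell. In edgeR 5004 of 24431 genes passed, 2341 higher and 2663 lower, 258 and 344 by 2-fold or more. By library size only the split was 1707 higher and 3643 lower, with RLE size factors 2660 higher and 2280 lower, and in DESeq2 2757 higher and 2391 lower. The count was 2632, 3234 and 2514 without replicates 1, 2 and 3 of all groups. The interaction of genotype and stage passed for 6219 genes, and for 1645 and 1878 without replicates 1 and 2. Among genes that carry no clone or locus symbol it was led by lbh, hif1al and hsp90aa1.2.

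The wild-type course shows what the genotype effects were measured against. From 1 somite to 25 hpf the largest rises included the muscle genes aldoab (log2 12.06 ± 0.22) and mylpfa (11.84 ± 0.18) and the globin hbbe3 (at least 2040-fold), while the paraxial mesoderm regulators msgn1 (-6.11 ± 0.14) and tbx16 (-6.01 ± 0.15) fell. From 25 hpf to 2 day they included the lens crystallin genes crygm2d15 at least 1460-fold and crygm2d2 at 10.07 ± 0.22 log2, and prtga fell (-5.77 ± 0.20). From 2 to 5 day they included the digestive enzyme genes prss59.1 at 16000-fold (counting interval 5470 to 77500) and amy2a at 6530-fold (2240 to 31700), while the hatching enzyme gene he1a was 5630-fold lower (1930 to 27300). From 5 to 9 day the globin hbz (9.18 ± 0.30) and the cholesterol synthesis gene sqlea (4.47 ± 0.29) rose and abcg2a fell (-2.72 ± 0.15). From 9 to 14 day the adult globins hbaa1 (10.99 ± 0.73) and ba1 (10.61 ± 0.48) rose and the embryonic globins hbae1 (-5.26 ± 0.36) and hbae3 (-4.21 ± 0.35) fell.

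These steps had 15173 of 19730, 12003 of 20106, 13083 of 21458, 11019 of 22342 and 3759 of 22399 genes past the edgeR threshold. Higher and lower counts were 8236 and 6937, 6152 and 5851, 6613 and 6470, 5673 and 5346, and 2087 and 1672, all in step order. With library size only the splits were 9928 and 5147 from 1 somite to 25 hpf, 4439 and 6583 from 5 to 9 day, and 1355 and 4519 from 9 to 14 day, where the median of all genes stood at 0.42, -0.13 and -0.22. The count from 9 to 14 day was 2450 and 2416 without 9 day wild type 2 and 3, and 2414 without 14 day wild type 3. The 9 day count stood lowest among the mutant comparisons, although 76.1% of simulated 2-fold changes were recovered at that stage.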

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

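The reading of kctd15a transcripts was chosen after the gene level was seen, and the other tests in this part before. The mutant effect differed between stages for 6219 genes in the interaction test of edgeR, and 565 of these were called higher at one stage and lower at another. In 25 regroupings of genotype labels within stages, the real one included, 1 gave as many interaction genes (6219, with at most 172 in any other), and 1 of 25 gave as many genes for the averaged effect (5004, with at most 5). That is the smallest share 25 regroupings can give and lies under 0.05, so chance is argued against for the averaged effect. For the interaction, regrouping also breaks up the effect averaged over stages. It therefore stands for no genotype effect at any stage, and cannot decide whether one effect shared by all stages would give as many interaction genes. Regrouping cannot separate the lesion from parental background or time of collection. Without replicates 1 and 2 of all groups the interaction gave 1645 and 1878 genes, and without replicates 1, 2 and 3 the averaged effect gave 2632, 3234 and 2514.

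The 10 genes with the smallest interaction p, among genes that carry no clone or locus symbol, are given with their effects at the stages where they passed. lbh (interaction adjusted p = 3.35e-13) changed by -2.72 ± 0.12 at 1 somite and lay between -0.24 and 0.25 elsewhere. hsp90aa1.2 (2.26e-12) changed by -3.12 ± 0.14 at 1 somite and by 0.30 ± 0.09 at 25 hpf, and cacna1ba (4.88e-12), a neuronal calcium channel gene, by -4.35 ± 0.31 and -1.24 ± 0.16. gstp1 (5.27e-11) changed by -2.32 ± 0.11 at 1 somite, 0.25 ± 0.08 at 25 hpf and -0.45 ± 0.10 at 5 day. The collagen gene col12a1a (7.62e-12) changed by 3.99 ± 0.30 at 1 somite and 0.42 ± 0.10 at 5 day, and sulf2b (9.01e-11) by 4.40 ± 0.29 at 1 somite and 0.39 ± 0.10 at 25 hpf, with 0.38 ± 0.11 at 5 day. fkbp16 (1.68e-11) rose by 1.62 ± 0.36 at 1 somite and fell at 25 hpf (-4.50 ± 0.28). hif1al (2.22e-12) changed by -0.97 ± 0.10 at 5 day and 1.53 ± 0.14 at 14 day, and the transcriptional repressor bcl6ab (2e-11) by -1.35 ± 0.15 and 1.46 ± 0.15 at these stages. serpinh1b (3.94e-10) changed by -0.91 ± 0.10 at 1 somite, 0.31 ± 0.08 at 25 hpf, 0.63 ± 0.14 at 2 day and -2.12 ± 0.14 at 14 day.

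The transcript table, which no comparison above uses, was read for kctd15a. Only transcripts whose accessions the RefSeq gene table lists for kctd15a were read. The most counted of these was higher in every mutant library than in every wild-type library. Its mutant over wild-type ratio was 1.42, 3.69, 3.71, 7.8, 4.91 and 3.33 from 1 somite to 14 day. The 5 day ratio rests on a spread wild type (6.01 ± 5.35 CPM, against 46.9 ± 2.71 in mutants), and the gene level was 3.89-fold higher there. The other kctd15a transcript read had group means of at most 1.15 CPM, too low to interpret. Its mean was lower in mutants at 1 somite, 2, 5 and 14 day and higher at 25 hpf and 9 day. The transcripts read fall short of the gene level. They held 53.5 and 0.718 CPM against 89.3 CPM in 1 somite wild type, and 6.01 and 1.07 against 19.4 in 5 day wild type. Some kctd15a counts thus lie in transcripts that were not read, whose change is unknown.

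For the single stages, 3 against 3 libraries make 10 splits, too few for a share under 0.05. At each stage 1 of 10 splits, the real one, gave as many genes: 2285, 2564, 1388, 3014, 422 and 1073 from 1 somite to 14 day, with 0 in the highest other split. For the wild-type steps 1 of 10 gave as many: 15173, 12003, 13083, 11019 and 3759, with 0 in the highest other split except 1 from 5 to 9 day. For the gene lists, 3 of 10 splits gave as many lists at 1 somite (3 real, 4 in the highest other), 1 of 10 at 25 hpf (11 and 10), 3 of 10 at 2 day (9 and 9), 2 of 10 at 5 day (13 and 14), 4 of 10 at 9 day (10 and 16) and 7 of 10 at 14 day (11 and 13). At every stage but 25 hpf the number of lists past camera was thus no more than regrouping the same libraries can give. At 25 hpf 10 splits are too few to tell.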

How the results depend on the processing

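Fits without the 25 hpf or 5 day libraries and with libraries thinned to one total per stage were chosen after seeing the data. The genes named held their direction under every setting run for them: of 630 gene values, 628 kept their side of the threshold with RLE size factors, 566 with library size only, 623 with no filter on counts, 628 with a filter of 1 CPM in 3 libraries and 572 with DESeq2. Of 578 values, 558 and 560 did so with limma on the normalized table plus 0.5 and plus 2, and of 560 values 462 did with one fit of all 36 libraries. With single libraries left out, 2971 of 3720 did and 730 no longer passed, in fits with fewer samples. No median of a list past camera changed sign under RLE or library size only.

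Counts of genes moved by over 1.5 times under these settings, and the cause was not tested: the fit of all 36 libraries gave 1473 at 25 hpf, 3016 at 2 day, 750 at 9 day and 2705 at 14 day, DESeq2 gave 640 at 9 day, and library size only gave 5874 from 9 to 14 day in wild type. Besides the replicate block and left-out libraries, all other counts of genes stayed within 1.5 times, thinned libraries included (2117, 2203, 1231, 2792, 414 and 1014 from 1 somite to 14 day; at 25 hpf 2050 genes were called both ways). Without 25 hpf or 5 day libraries the averaged effect gave 4477 and 3814 genes and the interaction 4632 and 4424.

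No sign of pairing by replicate number was seen: same-numbered mutant and wild-type libraries had correlations of their deviations from -0.246 to 0.0746, 0 of 18 above 0.1, and 2 of 18 wild-type libraries correlated best with their own number. These values cannot show whether the libraries were collected or prepared in numbered pairs. With the replicate block the counts were 1317 at 1 somite, 790 at 2 day, 1636 at 5 day and 3598 for the interaction, and all other gene counts stayed within 1.5 times. With the replicate block, 525 of 630 values of named genes kept their side of the threshold.

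With an estimated correlation the number of lists past camera was 0 at 1 somite, 0 at 25 hpf, 0 at 2 day, 0 at 5 day, 0 at 9 day and 0 at 14 day, where 1, 4, 2, 1, 3 and 0 lists had an unadjusted p under 0.05. Correlation between the genes of a list widens that test. With fry, which asks whether a list moves and not whether it moves more than other genes, the number was 3 at 1 somite, 13 at 25 hpf, 2 at 2 day, 6 at 5 day, 3 at 9 day and 0 at 14 day.

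With each replicate left out in turn, the counts ranged from 1397 to 2862 at 1 somite, 1725 to 2411 at 25 hpf, 555 to 2497 at 2 day, 1381 to 4723 at 5 day, 205 to 375 at 9 day and 556 to 1059 at 14 day. Those of the wild-type steps ranged from 14595 to 15235, 10920 to 12223, 11649 to 13266, 9593 to 10248 and 2414 to 4031, that of the averaged effect from 2514 to 3234 and that of the interaction from 1645 to 4738. Lists past camera ranged from 1 to 3, 9 to 12, 8 to 10, 11 to 16, 10 to 14 and 9 to 12. The lowest counts of genes came without mutant 3 at 1 somite, wild type 1 at 2 day, mutant 2 at 5 day, mutant 1 at 9 day and wild type 3 at 14 day, and the highest counts of genes at 2 and 5 day without wild type 3. With 3 libraries per group, 7.46% of simulated 1.5-fold changes were recovered at 14 day and 53% at 25 hpf.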

Other observations

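The tests of library depth, of the stage offset, of the erythroid genes, of linkage and of the 5 day inflammation list were chosen after the result was seen, and the test of numbered copies before. Some groups without a list call still held large single changes. At 5 day, 7 of 22 pigment cell genes rose and 3 fell (camera adjusted p = 0.0672), and 10 of 29 ionocyte and epidermis genes rose and 6 fell (0.137). The neural crest and neural plate border gene pax7b rose at that stage (0.83 ± 0.16). At 14 day the globin hbbe1.1 fell (-3.44 ± 0.43), in a list with 2 of 21 genes risen and 2 fallen (0.743).

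Calls were shared between stages more often than independence gives. Over the 15 pairs of stages, overlaps of calls in the same direction were 1.95 to 17.1 times expectation, and those in opposite directions 0.434 to 1.7 times. Across 24431 genes, which are not independent replicates, the log2 fold changes of 9 and 14 day correlated at 0.504, those of 5 and 9 day at 0.415 and of 5 and 14 day at 0.373, with 0.109 for the lowest pair, 1 somite and 5 day. No p was computed for these correlations.

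At 25 hpf, mutants stood ahead of wild type along the wild-type course from 1 somite to 2 day: the slope of the mutant shift on that course was 0.0337 of the step (r = 0.146 and rho = 0.157 across 24431 genes), positive in 9 of 9 library pairs (0.0284 to 0.0399), against at most 0.00574 between libraries of one genotype. The 9 pairs of a stage reuse the same libraries and are not 9 observations. All 9 on one side means only that the groups did not overlap, which chance alone gives in 10% of such comparisons. The lower depth of the mutant libraries is argued against as the cause of the 25 hpf slope, since thinning to one total left a lowest pair slope of 0.0288 (slope 0.0346, at most 0.00623 within genotypes). Whether a developmental stage offset is the cause stays open. Against flat genes, the median shift of 8630 genes that rise on the course was 0.0134 to 0.0811 log2 in the 9 pairs, and that of 5785 genes that fall was -0.0837 to -0.0208, but libraries of one genotype differed by up to 0.0249 and 0.0438. This test replaced the slope over genes in no list, which only restated the pattern. Whether an offset accounts for the erythroid rise stays open too: the slope predicts 0.11 log2 and 1.29 was observed, but no wild type was sampled between 25 hpf and 2 day to show a peak there. That 66.7% (8 of 12) of the erythroid genes that change between these stages shifted the same way decides nothing, since 19 of 20 erythroid genes were higher in mutants, and the erythroid mean of mutants (1.29 above the higher of both wild-type means) could not decide either. At 2 day the slope was 0.0187 (7 of 9 pairs positive; within genotypes up to 0.0444), at 5 day -0.123 (0 of 9; -0.192 to -0.0444, within genotypes up to 0.103) and at 9 day -0.0837 (0 of 9; within genotypes up to 0.0692), and an effect of the lesion on the pace of development was not tested apart from a difference in time of collection.

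The low inflammation list of 5 day mutants may come from raised wild-type libraries. The wild-type mean lay 1.26 log2 above that of wild type at 2 and 9 day, with an SD of 0.26 among the libraries, whereas the mutant mean lay at -0.19 from that of mutants at those stages. At 14 day, which this comparison leaves out, the list stood at 3.34 ± 0.13 in wild type and 3.04 ± 0.12 in mutants. A single library is argued against, since the lowest wild-type library stood 1.26 above the highest mutant library. Whether mutants were behind on the wild-type course stays open: the 5 day slope predicts 3.47% of the shift (-0.05 of -1.56), but the list peaks at 5 day in wild type, so a slope from 2 to 9 day could not decide, and 5 day mutants (2.42 ± 0.19) lie near 2 day wild type (2.5 ± 0.12). Whether the wild-type animals met an infection or injury, or mutants lacked a response all animals would mount at this stage, stays open and untested.

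At 4 or more stages 136 genes were called in one direction and never in the other (68 higher, 68 lower; 0.853 expected if stages were independent), and 16 at all 6 stages (10 higher, 6 lower), among them map1lc3b, kctd15a and kbtbd7. kbtbd7 stood at 0 to 0.15 CPM in mutants and 2.62 to 6.9 CPM in wild type, as group means over the stages. LOC or clone symbols made up 61% of the 136 genes and 32.9% of all genes. Linkage to the kctd15 loci is argued against as the whole cause, for the 72 of 136 genes with a place in the reference: 4.17% (3 of 72 placed genes) lie among the 100 nearest genes on either side of kctd15a or kctd15b, against 1.92% of 18061 placed genes (Fisher's exact test, two-sided, p = 0.161), and the 72 lie on 24 of 25 chromosomes. For the genes without a place, linkage stays open. Reads shared between numbered copies could account for some, as in 2 of 5 genes with such copies the family total moved by less than 0.5 times as much on the log2 scale. A difference in parental background between the mutant and wild-type lines stays open, untested, as does a lasting effect of the lesion.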
